A study of Homo sapiens with 6 samples.

How the data were processed

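RNA was profiled in 6 cultures of Kelly, a human neuroblastoma line that carries an amplified MYCN gene and a mutated ALK receptor gene. The labels give 3 groups of 2 biological duplicates: sensitive cells in DMSO, cells resistant to the ALK inhibitor TAE684 kept in TAE684 at 1 µM, and resistant cells in the BET bromodomain inhibitor JQ1 at 2.5 µM, each for 24 h. The labels do not say whether TAE684 was also present in the JQ1 group, so the JQ1 group is described below as the arrays labelled resistant JQ1. Groups were read from the sample labels. Replicate numbers came from the same labels.

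Per the labels' protocols, total RNA was spiked with ERCC control RNA, and biotinylated RNA was prepared from 100 ng with a 3′ in vitro transcription kit and hybridised to Affymetrix PrimeView arrays. The authors deposited 1 table of array intensity values on a linear scale, with 49495 probe sets in 6 columns. The submitters' processing notes name MAS5, the affy package and R 3.1.3. How the arrays were scaled to each other is not given in the sources used here. The ERCC probe sets lay at nearly equal levels on the 6 arrays while the gene medians did not, so a fold change on the deposited scale is relative to the spike-in as much as to other genes. No other per-sample columns were in the table.

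Of the 49495 probe sets, 100 were ERCC and 102 were other controls, and these stayed out of the tests. Of the remaining 49293, the platform annotation gave 1 gene symbol to 45278, several to 1333 and none to 2682, which are unnamed here. The single symbols numbered 18244, and 18201 of them were found in the reference gene table of assembly GRCh38.p14, which was used only for names and for the order of neighbouring genes. A probe set was tested if it reached the 30th percentile of its array on at least 2 arrays. The probe set with the highest mean over all 6 arrays stood for its gene, which left 14785 genes, 8911 of them with several passing probe sets. Histone genes are near-identical copies of each other, and their probe sets may read more than 1 gene, so single histone genes are uncertain.

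Values were taken as log2(value + 1), which understates the change of dim genes. One limma model with 3 group means was fitted to all 6 arrays (lmFit and eBayes with an intensity trend, limma 3.58.1, R 4.3.3), and p-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison at 0.05. The model had 3 residual degrees of freedom. On the deposited scale the spread was dominated by differences in overall brightness between arrays of a group, limma pooled it fully across genes, and the smallest adjusted p-values there are too small to be taken literally. After quantile normalization of the gene probe sets the prior degrees of freedom were 7.3. Because the deposited scale moved most genes in one direction, every comparison is also given after quantile normalization, and such a difference is called relative, since it is relative to the other genes of the array. Adjusted p-values in the report are limma's, and those of relative differences come from the quantile-normalized fit unless the deposited scale is named. The number of arrays limits the precision; with 2 arrays against 2, an exact permutation test of a single value cannot give a two-sided p below 0.333, and 33.3% of unchanged genes have groups that do not overlap.

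Before the data were examined, 48 gene lists were fixed, with 1462 entries, of which 1314 matched a symbol. Each list was tested with limma's camera at a preset correlation of 0.01 over all lists of a comparison and again with an estimated correlation. The named genes are, per comparison, the 10 largest rises and the 10 largest falls on the deposited scale among genes with adjusted p under 0.05 and non-overlapping groups, the fixed genes ALK, MYCN, MYC, CTCFL, CTCF, BRD2, BRD3 and HEXIM1 (1 further fixed gene is not reported here), and for lists described in detail up to 4 members with the smallest p. That p is from the deposited scale, where most calls of a comparison ran the same way, so the members named can over-represent that direction. Not all of the largest rises and falls are written out. Genes named outside this rule are marked as chosen after their values were seen.

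The fit was tested on simulated data built from the measured means and spreads of the 14785 genes, with 200 genes changed between resistant TAE684 and sensitive arrays. On the deposited scale 41.8% of 2-fold and 98.5% of 4-fold changes were recovered with 4 false calls. On the quantile-normalized scale 43.3% of 1.5-fold and 95.5% of 2-fold changes were recovered with 24 false calls. The simulated noise was independent between genes and left out brightness differences shared by the genes of an array. The false calls therefore do not measure the error rate on the real arrays. The camera and window steps were tested on simulated data too.

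The alternatives were another pseudocount of 32, no filter and a 50th percentile filter, the mean of a gene's probe sets, no intensity trend, robust moderation, only the 4 arrays compared, the replicate number as a block, each array left out in turn, and scaling by quantiles, array medians or ERCC means. Scaling by hybridization control probe sets, alternatives on top of the quantile scale and the windows of neighbouring genes were chosen after seeing the data.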

Results

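Gene expression was measured on 6 arrays of the neuroblastoma line Kelly, 2 per group. The question was how cells resistant to ALK inhibition differ in expression from sensitive cells, and what the BET inhibitor JQ1 changes in the resistant cells. The gene probe sets had a median signal of 64.3 ± 7.2 (SD, n = 2) in the sensitive group, 32.6 ± 3.7 in the resistant TAE684 group and 52.6 ± 9.2 in the group labelled resistant JQ1. The mean log2 signal of the ERCC spike-in was 6.73, 6.69 and 6.70 in the same order. Over the 14785 genes, the median log2 difference was -1.11 for resistant TAE684 minus sensitive arrays, 0.81 for JQ1 minus TAE684 arrays and -0.27 for JQ1 minus sensitive arrays. The first shift depended on signal, from -0.59 in the dimmest decile of the genes to -1.44 in the decile with a mean signal of 124.5. Relative differences, taken after quantile normalization, set this shift aside. The 3′ to 5′ signal ratio of ACTB, a sign of RNA integrity, was 1.60 ± 0.03 in sensitive, 1.91 ± 0.28 in TAE684 and 1.58 ± 0.14 in JQ1 arrays (SD, n = 2). At 2.11 and 1.71, both TAE684 arrays lay above the highest of the other arrays, 1.68, in each comparison with that group given here. The same ratio of GAPDH was nearly level, at 0.96 in sensitive, 0.99 in TAE684 and 0.98 in JQ1 arrays.

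**Figure D1:**
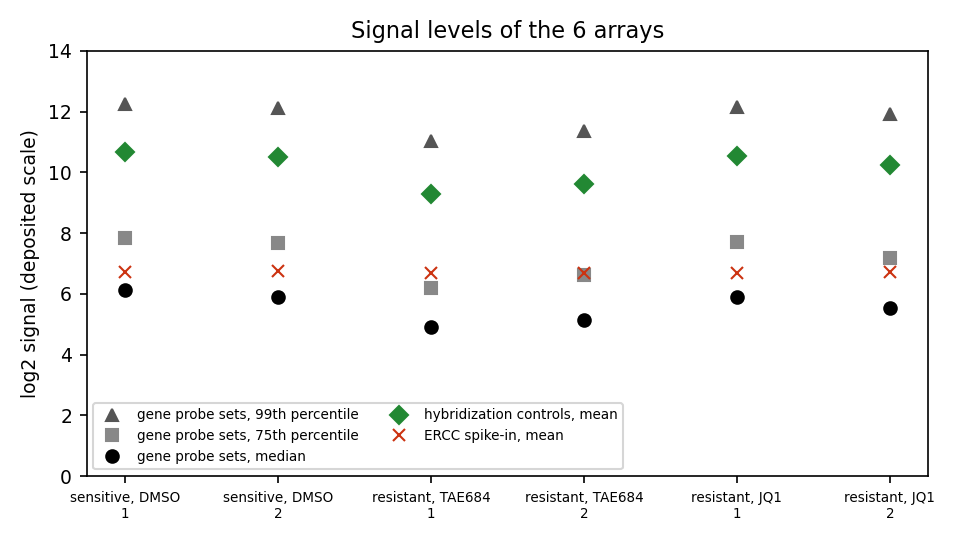
Log2 signal on the deposited scale for each of the 6 arrays: the 99th percentile, 75th percentile and median of the gene probe sets, and the means of the hybridization controls and of the ERCC spike-in. The ERCC means lie between 6.68 and 6.74 on all 6 arrays, while the gene levels and hybridization controls are lowest on the 2 resistant TAE684 arrays.

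Across genes, which are not independent replicates, the quantile-normalized values of arrays correlated with r = 0.995 within the sensitive group, 0.988 within the TAE684 group and 0.985 within the JQ1 group. Between groups, r was 0.966 to 0.975 for sensitive and JQ1 arrays, 0.930 to 0.950 for sensitive and TAE684 arrays and 0.920 to 0.938 for TAE684 and JQ1 arrays. The arrays labelled resistant JQ1 had a higher r with each sensitive array than with each TAE684 array.

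Resistant cells in TAE684 were compared with sensitive cells in DMSO, a comparison in which line and drug change together. Several genes rose from low signals in sensitive arrays. NEUROD4, a proneural transcription factor, had a signal of 786 ± 106 against 22.9 ± 3.91 in sensitive arrays (SD, n = 2; relative log2 difference 6.09, adjusted p = 1.1e-08). PKIB, an inhibitor of protein kinase A, read 1291 ± 282 against 36.1 ± 5.19, and CTCFL, the germline paralogue of the chromatin insulator CTCF, read 619 ± 97.8 against 38.7 ± 6.46 (relative log2 difference 5.14, adjusted p = 1.4e-08). In the other direction, the immediate early gene EGR1 read 21.8 ± 3.87 against 1038 ± 163 and the receptor tyrosine kinase RET 68.5 ± 13.5 against 2703 ± 382. ALK, the target of TAE684, read 46.9 ± 13.1 against 335 ± 46.0, a relative log2 difference of -1.68 (SE 0.165, adjusted p = 3.9e-05).

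The other genes with the largest rises included CER1 (relative log2 difference 5.34), PTX3 (4.87), INHBE (4.94), MYL1 (4.57), RPRM (4.64) and CEBPD (4.53), and the largest falls included ARMCX1 (-5.27), DOK4 (-4.66), TCEAL7 (-5.09), TMT1A (-4.36), FMOD (-4.61), SLC8A3 (-4.39), TRIM29 (-4.11) and the hyaluronan receptor CD44 (-4.62). CD300LG was also among the rises, but only 1 of its 3 probe sets was higher, and its deposited-scale call ended with the mean of its probe sets (adjusted p = 0.0507). For CTCFL, 6 of 7 probe sets were higher. CTCF itself was lower by a relative log2 difference of -0.41 (adjusted p = 0.0331). It lies on chromosome 16 among neighbours that were lower together, in windows described below with medians of -0.45 and -0.56. MYCN, the amplified driver of this line, stayed among the brightest genes, with a signal of 4617 ± 550 against 10240 ± 488. Its difference was -1.15 on the deposited scale and -0.50 as a relative value (adjusted p = 2.1e-04). With array medians centred it did not pass (adjusted p = 0.137), and with hybridization controls centred it was 0.02. MYC lay under the 30th percentile of both sensitive arrays and was higher in TAE684 arrays, at 35.3 ± 3.89 against 15.2 ± 5.00 (relative log2 difference 1.91, adjusted p = 7.4e-05). The BET genes BRD2 and BRD3 changed sign with the scale, from -1.19 and -0.90 on the deposited scale to relative differences of 0.32 and 0.64 (adjusted p = 0.0192 and 7.6e-04). Neither passed with array medians centred (BRD2 -0.24, adjusted p = 0.269; BRD3 0.06, 0.833) or with hybridization controls centred (BRD2 -0.02, 0.920; BRD3 0.28, 0.100), so both are called higher after quantile normalization alone. Without sensitive replicate 1 BRD3 did not pass on the deposited scale (adjusted p = 0.170), nor without sensitive replicate 2 (0.0584) or TAE684 replicate 1 (0.0718). Of the 83 genes named for this comparison 13 lay under the 30th percentile of both arrays of a group, so the sizes of their differences are uncertain. These were NEUROD4, PTX3, INHBE, MYL1, MYC, NEUROG1 and LIN28A in sensitive arrays and ARMCX1, TCEAL7, CD44, COL4A1, PAGE1 and TKTL1 in TAE684 arrays. HEXIM1, at -1.54 on the deposited scale, did not pass as a relative value (-0.22, adjusted p = 0.177).

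Of 14785 genes 12833 differed on the deposited scale, 193 higher and 12640 lower in TAE684 arrays. After quantile normalization 3890 differed, 1865 higher and 2025 lower, and 555 and 599 of these changed at least 2-fold. With array medians centred the split was 1753 higher and 4429 lower, and with hybridization controls centred it was 2621 and 2804. Without sensitive replicate 1 the counts were 7813 on the deposited scale and 1938 after quantile normalization, and the latter was 2148 without sensitive replicate 2 and 2418 without TAE684 replicate 1.

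**Figure D2:**
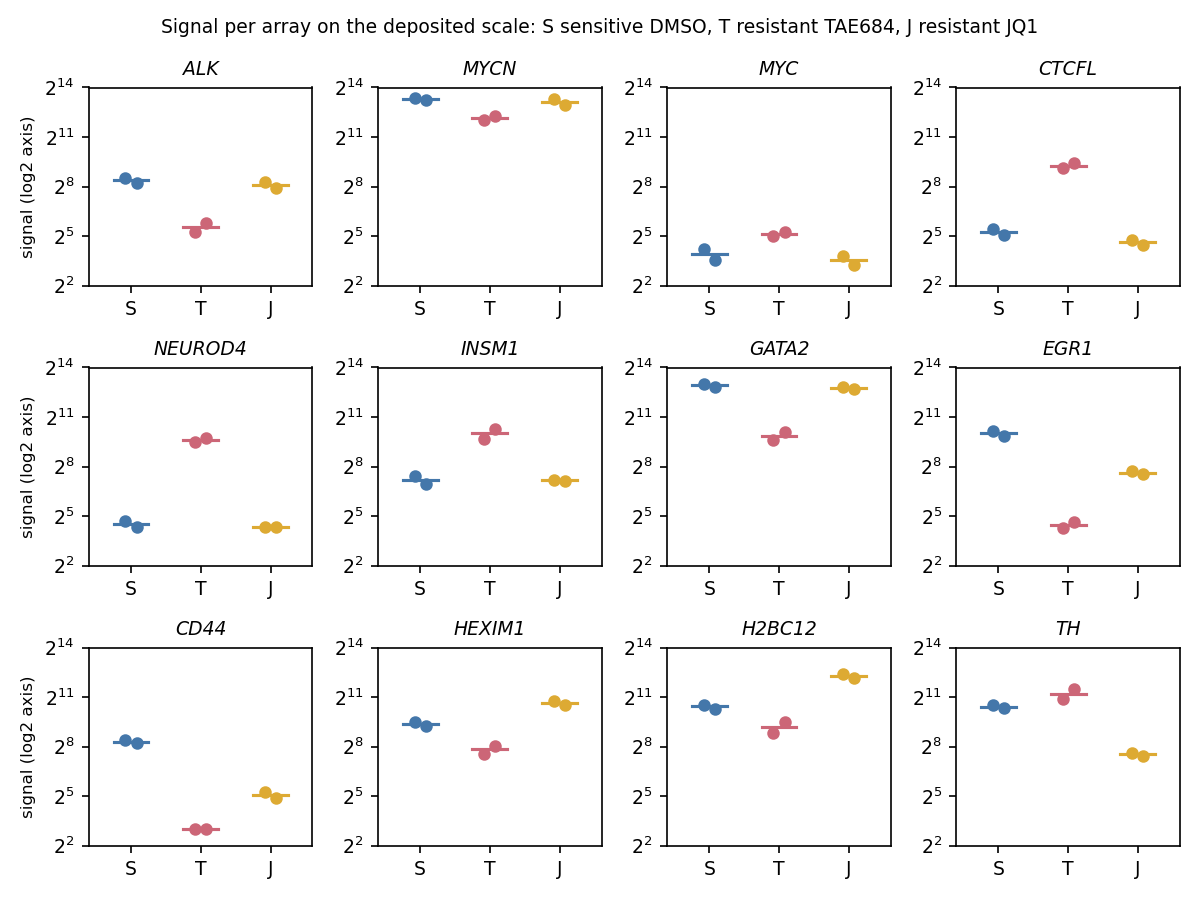
Signal of 12 genes on each array on the deposited scale, on a log2 axis. Points are single arrays and lines are the means of the 2 arrays of a group; CTCFL and NEUROD4 are highest on the resistant TAE684 arrays, HEXIM1 and H2BC12 on the JQ1 arrays, and EGR1 on the sensitive arrays.

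Transcription factors of the adrenergic state, which define sympathetic neuroblast identity, moved in both directions. After quantile normalization 12 of 22 tested members were lower and 5 higher (15 and 6 adjusted over the list alone), with camera adjusted p = 0.0352, and adjusted p = 0.589 with an estimated correlation. The list did not pass on the deposited scale (adjusted p = 0.068). GATA2, HAND1, PHOX2A and INSM2 had relative log2 differences of -2.01, -1.37, -1.18 and -0.92. INSM1, a zinc finger factor of neuroendocrine cells chosen after its values were seen, went the other way at 1035 ± 303 against 147 ± 35.6 (relative log2 difference 4.17, adjusted p = 1.1e-07). Genes of the noradrenergic phenotype split evenly, with 10 of 25 higher and 10 lower (the same adjusted over the list alone), and did not pass (adjusted p = 0.942, median 0.06, mean -0.15); deposited values gave 3 higher and 17 lower. RET (-4.02), the electron carrier CYB561 (-3.89), the vesicular monoamine transporter SLC18A2 (-3.69) and the noradrenaline transporter SLC6A2 (-2.65) were lower. These members were named by p on the deposited scale, where falls prevailed, and do not stand for the list.

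Neural stem and proneural factors had 12 of 33 members higher and 4 lower (12 and 5 adjusted over the list alone), with camera adjusted p = 0.0453 and adjusted p = 0.740 with an estimated correlation. The list's median was -0.05 and its mean 0.61, so a minority of members carried the mean. The majority turned with the scale, with 7 higher and 20 lower on the deposited one. NEUROD4 was followed by NEUROG1 (3.83) and the RNA-binding protein LIN28A (3.11), while NES was lower (-0.97). Among mesenchymal-state transcription factors 10 of 29 were higher and 4 lower (10 and 5 adjusted over the list alone), which did not pass (adjusted p = 0.486, median -0.04, mean 0.27), and the deposited counts were the other way, 4 higher and 20 lower. SNAI2 was higher (3.88), and TWIST1 (-1.84), VIM (-1.86) and FOSL2 (-1.68) were lower. Here too the members were named by p on the deposited scale and do not stand for the list. SOX9, chosen after its values were seen, was higher (2.66), a call that ended on the deposited scale without sensitive replicate 2 (adjusted p = 0.0571). Mesenchymal and extracellular matrix genes had 12 of 36 lower and 6 higher (13 and 6 adjusted over the list alone), camera adjusted p = 0.0352, and adjusted p = 0.740 with an estimated correlation. CD44, the type IV collagens COL4A2 (-3.78) and COL4A1 (-3.44) and the gelatinase MMP2 (-3.10) were the members with the smallest p.

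Transcripts that report ERK signalling had 10 of 23 lower and 3 higher (10 and 3 adjusted over the list alone), camera adjusted p = 0.0453, and adjusted p = 0.859 with an estimated correlation. Relative log2 differences were -4.52 for EGR1, -2.32 for FOS, -1.94 for the phosphatase DUSP4 and -1.69 for SPRY4. Receptor tyrosine kinases had 6 of 35 higher and 7 lower (6 and 9 adjusted over the list alone) and did not pass (adjusted p = 0.512). ROR2 (-1.25) and EPHB3 (-1.43) were lower beside RET and ALK. All members named here were lower, so they do not stand for the list. MYC and MYCN targets had 24 of 51 lower and 5 higher (26 and 6 adjusted over the list alone), camera adjusted p = 0.0453, and adjusted p = 0.740 with an estimated correlation. MCM3 (-0.83), LDHA (-0.66), PES1 and ODC1 (-0.49) were among them. Oxidative phosphorylation genes had 12 of 42 lower and 3 higher (15 and 3 adjusted over the list alone), camera adjusted p = 0.0453, and adjusted p = 0.740 with an estimated correlation, with COX4I1 (-0.92), UQCRC1 (-0.85), ATP5PB (-0.58, 2 of 4 probe sets lower) and NDUFB5 (-0.51) lower. Cancer-testis antigens, the class CTCFL belongs to, had 2 of 20 higher and 6 lower (3 and 7 adjusted over the list alone) and did not pass (adjusted p = 0.675), with PAGE1 (-2.17), CTAG2 (-2.40) and TKTL1 (-1.16) lower. On the deposited scale the calls of the MYC target, oxidative phosphorylation and matrix lists ended with hybridization controls centred (adjusted p = 0.142, 0.798 and 0.178). The first 2 also ended with array medians centred (0.153 and 0.367) and from the 4 arrays compared (0.255 and 0.255), and the last 2 with the mean of a gene's probe sets (0.0575 and 0.0807). The MYC target call also ended without sensitive replicate 1 (0.0604), sensitive replicate 2 (0.146), JQ1 replicate 1 (0.265) or JQ1 replicate 2 (0.209), and the oxidative phosphorylation call without the last 3 of these (0.0524, 0.265 and 0.209).

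**Figure D3:**
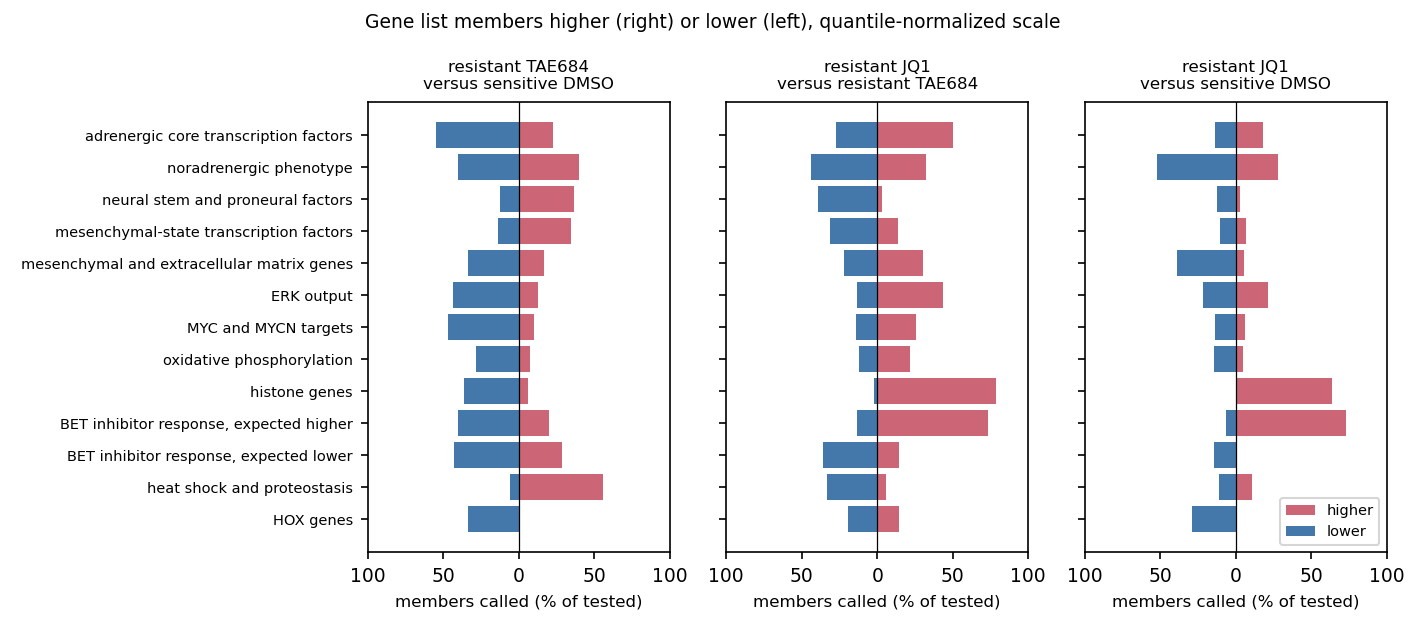
Share of the tested members of 13 gene lists called higher (right) or lower (left) in each of the 3 comparisons, on the quantile-normalized scale. Histone genes have 37 of 47 members higher in JQ1 than in TAE684 arrays and 30 of 47 higher in JQ1 than in sensitive arrays.

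Genes that lie next to each other on chromosomes were shifted together in the TAE684 arrays. In windows of 100 neighbouring genes, taken every 50 genes so that neighbouring windows overlap and do not count separate regions, 81 of 274 had a median relative difference past a threshold of 0.159, set from 1000 random gene orders, where 0.27 windows would be past it by chance. Of the 81 windows 54 were higher and 27 lower. Both TAE684 arrays passed the threshold separately in 47 windows, 23 higher and 24 lower. On chromosome 3, 6 windows from IL5RA to KCTD6 were lower by medians of -0.73 to -0.42, and 6 of chromosome 16 from ZNF646 to PRDM7 by -0.62 to -0.33. On chromosome 12, 7 windows from ATP5F1B to ZNF268 were higher by 0.33 to 0.61. Medians on chromosome 22 were lower by -0.40 to -0.27 in 7 windows. Some genes named above lie in these lower windows: CTCF and COX4I1 on chromosome 16, UQCRC1 on chromosome 3 and PES1 on chromosome 22. Their falls may in part be those of their neighbours. In the arrays labelled resistant JQ1 the same windows lay between -0.08 and 0.00 on chromosome 3, -0.03 and 0.02 on chromosome 16, -0.03 and 0.11 on chromosome 12, and -0.10 and -0.01 on chromosome 22, relative to sensitive arrays. Other windows kept part of their shift: of the 7 windows past the lower threshold of JQ1 minus sensitive arrays, 0.112, 6 on chromosomes 1, 2, 5 and 14 were among the 81 of the TAE684 arrays, in the same direction, with 0.444 to 0.551 of the shift kept. Their medians were 0.16 to 0.27 on JQ1 replicate 1 and -0.08 to 0.05 on replicate 2. In TAE684 arrays too they were larger on replicate 1, at 0.305 to 0.459, than on replicate 2, at 0.075 to 0.207. The kept part thus came mainly from JQ1 replicate 1. The other of the 7 windows, from NOL7 to H2AC17 on chromosome 6, was higher by 0.22 and was at -0.05 in TAE684 arrays. It ends at a histone gene, and 30 of 47 histone genes were higher in JQ1 than in sensitive arrays. How many of its genes are histone genes was not counted. Of the genes in the 47 windows, 79.4% moved with their window in TAE684 arrays and 53.9% in JQ1 arrays. The first share is high by construction, since the windows were chosen on the same values. Both shares rest on the same sensitive arrays and count genes of overlapping windows more than once.

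**Figure D4:**
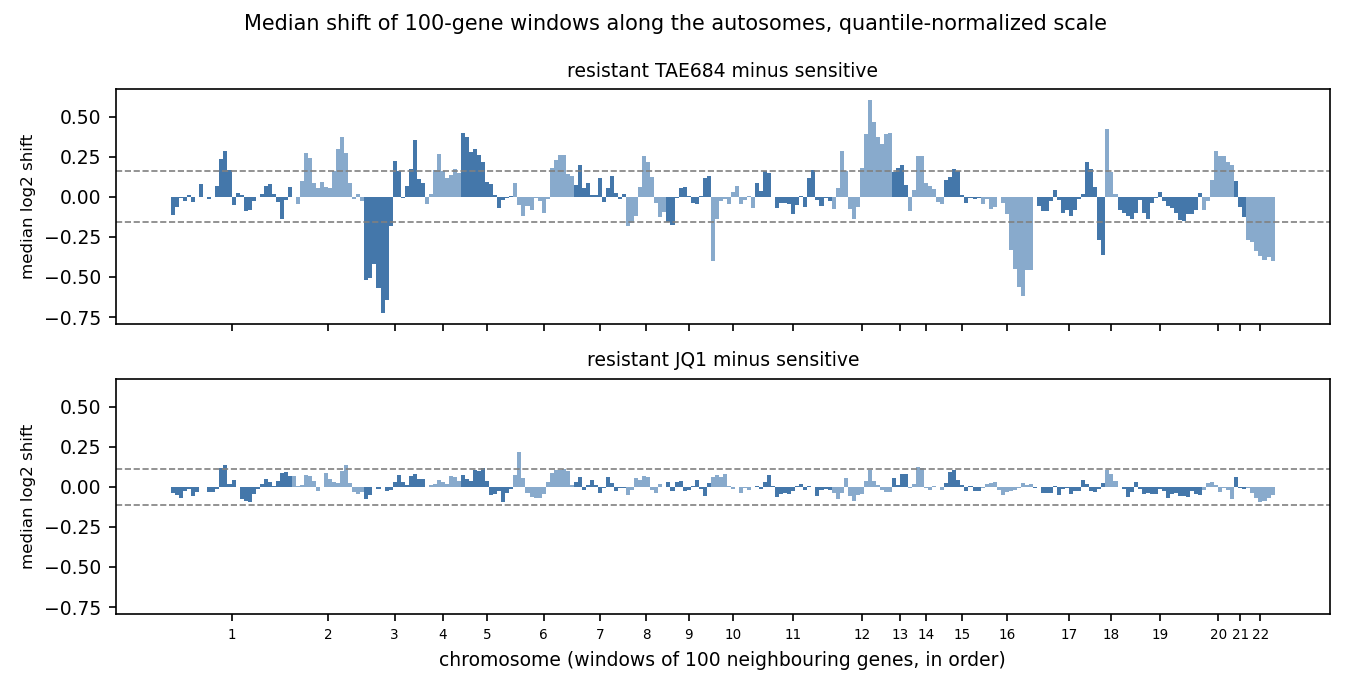
Median relative log2 difference of windows of 100 neighbouring genes in chromosome order, for resistant TAE684 minus sensitive arrays (top) and JQ1 minus sensitive arrays (bottom). Dashed lines are the thresholds of 0.159 and 0.112 from random gene orders; 81 windows pass in the top panel and 7 in the bottom panel.

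The arrays labelled resistant JQ1 were then compared with the resistant TAE684 arrays. Some of the genes with the largest rises in TAE684 arrays were low in JQ1 arrays. CTCFL read 24.7 ± 4.21 against 619 ± 97.8 (SD, n = 2; relative log2 difference -5.55, adjusted p = 1.4e-08), NEUROD4 20.2 ± 0.314 against 786 ± 106, and the transcription factor CEBPD 11.5 ± 3.51 against 312 ± 41.6. Higher genes included ARMCX1 (relative log2 difference 4.84), CYB561 (3.20) and DOK4 (3.70). HEXIM1, an inhibitor of the elongation factor P-TEFb whose transcript is a common marker of BET inhibition, read 1593 ± 150 against 227 ± 50.4 (relative log2 difference 1.80, adjusted p = 1.3e-06). ALK was higher by 1.58 (adjusted p = 5.0e-05) and MYC lower by -2.12 (adjusted p = 2.9e-05).

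Under the 30th percentile of both arrays of a group, where sizes are uncertain, were 13 of the 55 genes named: NEUROD4, CTCFL, INHBE, CEBPD, MYC, NEUROG1, LIN28A, PROM1 and BHLHE41 in JQ1 arrays and ARMCX1, TCEAL7, CRTAC1 and ITPR1 in TAE684 arrays. Further large falls were PKIB (-5.56), CER1 (-5.53), ARHGAP36 (-5.23), DACT1 (-4.91), INHBE (-4.87) and CNTN2 (-4.87), and further rises CRTAC1 (4.40), TMT1A (3.91), TCEAL7 (4.48), METRNL (4.17), ITPR1 (4.12), SLC8A3 (3.67) and SCARNA20 (3.56). MYCN differed by 0.97 on the deposited scale and by a relative 0.32 (adjusted p = 0.003), with 3 of 4 probe sets higher, and by 0.00 with hybridization controls centred. CTCF was higher by a relative 0.38 (adjusted p = 0.0388), beside medians of 0.33 and 0.49 in the chromosome 16 windows that hold it. BRD2 was higher by a relative 0.84 (adjusted p = 4.1e-05). BRD3 was at 1.13 on the deposited scale, at -0.02 as a relative value (adjusted p = 0.906) and at 0.16 with hybridization controls centred (0.312).

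Histone genes had 37 of 47 members higher and 1 lower (39 and 1 adjusted over the list alone), with camera adjusted p = 6.4e-15, and adjusted p = 0.763 with an estimated correlation. H2BC12, H2AC11, H1-2 and H2BC5 had relative log2 differences of 2.02, 2.84, 2.83 and 2.81. Genes expected to rise under BET inhibition, a list that shares histone members with the previous one, had 11 of 15 higher and 2 lower. Adjusted over the list alone these were 11 and 2, with camera adjusted p = 2.0e-05, and adjusted p = 0.763 with an estimated correlation. The thioredoxin-binding protein TXNIP was at 2.63. Genes expected to fall under BET inhibition had 5 of 14 lower and 2 higher and did not pass (camera adjusted p = 0.411). On the deposited scale 1 of these was lower and 8 were higher. ERK output transcripts had 10 of 23 higher and 3 lower (12 and 3 adjusted over the list alone), camera adjusted p = 0.0421, and adjusted p = 0.841 with an estimated correlation, with EGR1 (2.54), the neuropeptide precursor VGF (1.88), DUSP4 (1.56) and SPRY2 (1.18) higher; its deposited-scale call (adjusted p = 0.0288) ended with a pseudocount of 32 (0.0558) and with the 50th percentile filter (0.0846). Neural stem and proneural factors had 13 of 33 lower and 1 higher (13 and 2 adjusted over the list alone), camera adjusted p = 0.0421, and adjusted p = 0.782 with an estimated correlation, with a median of 0.07 and a mean of -0.73, against 18 higher and 8 lower on the deposited scale. NEUROD4, NEUROG1 (-3.94), LIN28A (-3.36) and PROM1 (-1.76) were lower. Without a filter PROM1 was at 0.396 on the deposited scale and did not pass (limma adjusted p = 0.141).

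Adrenergic core factors had 11 of 22 higher and 6 lower (11 and 7 adjusted over the list alone) and did not pass after quantile normalization (adjusted p = 0.276), and a deposited-scale call (adjusted p = 0.0422, and adjusted p = 0.989 with an estimated correlation) ended without any of 4 arrays, sensitive replicates 1 and 2 (0.157 and 0.159) and JQ1 replicates 1 and 2 (0.302 and 0.264). It ended as well with the 50th percentile filter (0.165), the mean of a gene's probe sets (0.0549), the 4 arrays compared (0.187), medians centred (0.112) and hybridization controls centred (0.124). GATA2 (1.94), INSM2 (1.52), PHOX2A (1.76) and HAND1 (1.20) were higher and INSM1 lower (-3.79). Mesenchymal-state factors had 4 of 29 higher and 9 lower (5 and 9 adjusted over the list alone) and did not pass after quantile normalization (adjusted p = 0.488, median 0.11, mean -0.45) but did, in the lower direction relative to all genes, on the deposited scale (adjusted p = 0.00244, and adjusted p = 0.989 with an estimated correlation), where 17 were higher and 6 lower, a call that ended with hybridization controls centred (adjusted p = 0.339); SNAI2 (-4.12), SIX4 (-3.43), BHLHE41 (-2.38) and SOX9 (-3.23) were lower and TWIST1 higher. In total 10175 genes differed on the deposited scale, 9830 higher and 345 lower, against 4494 after quantile normalization, 2248 higher and 2246 lower. With array medians centred 3937 were higher and 1520 lower, and with hybridization controls centred 2152 and 3060. The deposited-scale count was 5536 without TAE684 replicate 1 and 6016 without JQ1 replicate 1.

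The 2 steps ran in opposite directions for many genes. After quantile normalization 1252 genes were higher in TAE684 than in sensitive arrays and lower in JQ1 than in TAE684 arrays, where independent lists would share 283.3, and 1289 were lower and then higher, where 307.9 would be shared. Genes with the same direction in both steps numbered 90. On the deposited scale the opposite calls numbered 9617, where 4.5 and 8403.9 would be shared, and they numbered 5925 without sensitive replicate 1, 5046 without TAE684 replicate 1 and 5778 without JQ1 replicate 1. The steps share the TAE684 arrays with opposite sign, which by itself gives opposition, so part of the excess may come from those 2 arrays. Across genes the correlation of the steps was -0.796 against -0.5 in 100 simulations of unchanged groups. The covariance was -0.327 against -0.015, a difference of -0.312. Noise in these simulations was independent between genes, so they leave out noise shared by the genes of an array. Of the 555 genes higher by at least 2-fold in TAE684 arrays, CTCFL and NEUROD4 among them, 493 were called lower in JQ1 arrays, and the median second difference was 98.9% of the first in size. Of the 599 lower genes, such as CD44 and RET, 483 were called higher in JQ1 arrays, with a median of 74.9%.

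The arrays labelled resistant JQ1 were finally compared with the sensitive arrays. Histone genes led the rises. H2BC5 read 922 ± 84.4 against 196 ± 20.4 (SD, n = 2; relative log2 difference 2.57, adjusted p = 7.4e-06) and H2BC12 4994 ± 605 against 1377 ± 159 (2.29, adjusted p = 1.6e-06). HEXIM1 was higher at 1593 ± 150 against 656 ± 80.8 (relative log2 difference 1.58, adjusted p = 2.0e-05). The largest falls were in IGFBP5, an insulin-like growth factor binding protein, at 31.2 ± 8.75 against 397 ± 39.1, and the nociceptin receptor gene OPRL1 at 55.7 ± 4.08 against 519 ± 60.6. TH, the rate-limiting enzyme of catecholamine synthesis, read 184 ± 18.3 against 1358 ± 125 (relative log2 difference -2.46, adjusted p = 6.8e-06).

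ALK (relative log2 difference -0.10, adjusted p = 0.773), MYCN (-0.18, adjusted p = 0.0883), MYC (-0.20, adjusted p = 0.611), CTCF (-0.03, adjusted p = 0.931) and CTCFL (-0.42, adjusted p = 0.112) did not pass, which does not show that they were equal. MYC lay under the 30th percentile of all 4 arrays compared, CTCFL, THBS2 and HOXD11 under that of both JQ1 arrays, and SERPINI1 and H3C2 under that of both sensitive arrays, so the sizes of these differences are uncertain. BRD2 was higher by a relative 1.16 (adjusted p = 2.7e-05) and BRD3 by 0.63 (adjusted p = 0.00205), and neither passed on the deposited scale (adjusted p = 0.113 and 0.740). Other rises were DHRS2 (1.86), SERPINI1 (1.72), MIR7-3HG (1.78), SERTAD1 (1.93), PAG1 (1.86), DCXR (2.04) and SCG2 (1.92), and other falls SERPINF1 (-2.78), TNFRSF25 (-2.70), TG (-2.69), CIART (-2.70), SLC38A5 (-2.65) and TNS3 (-2.41).

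Of the histone genes 30 of 47 were higher and 0 lower (33 and 0 adjusted over the list alone), camera adjusted p = 5.3e-18, and adjusted p = 0.580 with an estimated correlation, with H2AC6 at 2.12 and H3C2 at 1.04. Deposited values gave 13 higher and 0 lower (15 and 0 adjusted over the list alone). Genes expected to rise under BET inhibition had 11 of 15 higher and 1 lower (12 and 2 adjusted over the list alone), camera adjusted p = 3.1e-08, and adjusted p = 0.580 with an estimated correlation. Of its 15 members, 7 were higher and 1 lower on the deposited scale. The member that went against the list's name was ZMYND8, a chromatin reader (-1.54). Mesenchymal and extracellular matrix genes had 14 of 36 lower and 2 higher (16 and 3 adjusted over the list alone), camera adjusted p = 1.6e-04, and adjusted p = 0.580 with an estimated correlation, with CD44 (-2.82), IGFBP5 (-3.29), THBS2 (-1.30) and COL4A1 (-1.48) lower. The noradrenergic phenotype had 13 of 25 lower and 7 higher (13 and 7 adjusted over the list alone), camera adjusted p = 0.00888, and adjusted p = 0.580 with an estimated correlation, with TH, DDC (-1.17; its deposited-scale call ended with the mean of its probe sets, adjusted p = 0.221), SLC18A1 (-1.39) and ADRA2A (-1.18) lower. HOX genes had 6 of 21 lower and 0 higher (6 and 0 adjusted over the list alone), camera adjusted p = 0.0193, and adjusted p = 0.713 with an estimated correlation, with HOXC8 (-1.86), HOXD3 (-1.50), HOXC4 (-1.26) and HOXD11 (-1.25) lower. Genes expected to fall under BET inhibition had 2 of 14 lower and 0 higher (5 and 0 adjusted over the list alone), camera adjusted p = 0.0419, and adjusted p = 0.580 with an estimated correlation; the list did not pass on the deposited scale (adjusted p = 0.166). Deposited-scale calls ended for the noradrenergic list without sensitive replicate 2 (adjusted p = 0.105) or JQ1 replicate 2 (0.0738) and with hybridization controls centred (0.130), and for the HOX list without a filter (0.137) and with those controls centred (0.0521). ERK output transcripts had 5 of 23 higher and 5 lower (5 and 5 adjusted over the list alone) and did not pass (adjusted p = 0.976), while EGR1 (-1.98), FOS (-1.10), SPRY4 (-0.79) and ETV4 (-0.60) were lower. These 4 had the smallest p on the deposited scale, where 4 members were called lower and 0 higher, so they do not stand for the list.

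In all, 1104 genes differed on the deposited scale between JQ1 and sensitive arrays, 83 higher and 1021 lower, and after quantile normalization 2158 differed, 889 higher and 1269 lower. With array medians centred 1161 were higher and 1398 lower, and with hybridization controls centred 628 and 1760. The deposited-scale count was 181 without sensitive replicate 1, 393 without sensitive replicate 2 and 735 without JQ1 replicate 2, and the count after quantile normalization was 748 without sensitive replicate 1 and 818 without sensitive replicate 2. Single genes lost deposited-scale calls when a sensitive array was left out. HEXIM1 did so without replicate 1 or 2 (adjusted p = 0.324 and 0.360), as did H2AC6 (0.112 and 0.0870), SERTAD1 (0.146 and 0.147), SCG2 (0.170 and 0.198), ADRA2A (0.0991 and 0.110), HOXC4 (0.295 and 0.0514), FOS (0.623 and 0.102), SPRY4 (0.329 and 0.0762) and ETV4 (0.333 and 0.132). Calls ended without replicate 1 for ZMYND8 (0.144), THBS2 (0.0570), DDC (0.0652), SLC18A1 (0.0579) and HOXD3 (0.0707), and without replicate 2 for PAG1 (0.146) and DCXR (0.127).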

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

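Centring on hybridization controls and the alternatives on top of quantile normalization were chosen after seeing the data; the others were fixed before. Scaling moved the counts of changed genes in all 3 comparisons, and leaving out 1 array moved that of JQ1 minus sensitive arrays further, to 181 of 1104. Against 12833 genes on the deposited scale for TAE684 minus sensitive arrays, quantile normalization gave 3890, median centring 6182 and hybridization control centring 5425. For JQ1 minus TAE684 arrays the same settings gave 4494, 5457 and 5212 against 10175, and for JQ1 minus sensitive arrays 2158, 2559 and 2388 against 1104. Opposite calls in the 2 steps numbered 2541, 3679 and 3209 against 9617. Requiring a 2-fold change, a stricter threshold by construction, left 5333 genes for JQ1 minus TAE684 arrays and 4821 opposite calls, and after quantile normalization 1154, 1329 and 475 genes in the 3 comparisons. ERCC centring moved no count by over 1.5 times.

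With 1 array left out, a fit in which the lone array is assumed to vary like the other groups, the counts on the deposited scale ranged from 7813 to 13146, 5536 to 11058 and 181 to 1586 in the 3 comparisons. After quantile normalization they ranged from 1938 to 5000, 3277 to 4994 and 748 to 2948. Opposite calls ranged from 5046 to 10393 and the correlation of the steps from -0.817 to -0.736. The replicate numbers did not pair the sensitive arrays with the others. Deviations of same-numbered arrays correlated at -0.119 for sensitive and TAE684 and -0.090 for sensitive and JQ1 arrays. For TAE684 and JQ1 arrays the value was 0.406, and 0.559 after quantile normalization, so same-numbered arrays of these groups deviated in part together. With the replicate block the counts were 11847, 7879 and 544, the last lower by over 1.5 times. After quantile normalization they were 4792, 5294 and 2889, against 3890, 4494 and 2158 without the block. The cause was not tested.

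Camera called 5, 11 and 6 lists in the 3 comparisons on the deposited scale and 0, 0 and 0 with an estimated correlation. For TAE684 minus sensitive arrays it called 13 after quantile normalization, 11 without a filter, 3 from the 4 arrays compared and 3 to 9 with 1 array left out. For JQ1 minus TAE684 arrays it called 5 after quantile normalization, 6 with medians centred, 6 with hybridization controls centred, 6 with the 50th percentile filter, 6 with the mean of probe sets, 7 with the replicate block and 5 to 12 with 1 array left out. With 1 array left out it called 5 to 8 for JQ1 minus sensitive arrays. The cause of these moves was not tested.

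Of 3251 values of named genes under these alternatives 3150 kept their side of the threshold with no turn counted. Another 58 lost and 15 gained a call, and 28 turned direction. For gene lists, with camera's direction, these numbers were 2589, 99, 40 and 5 of 2733. A turn was counted only where the main setting or the alternative passed. The first number thus includes turns of direction without a call in either setting. Some directions turned with the scale, as the shift of all genes makes possible. For TAE684 minus sensitive arrays BRD2 was 0.32 after quantile normalization, and BRD3 0.644, 0.056 and 0.275 after quantile, median and hybridization control scaling. MYCN was 0.021 with hybridization controls centred. In the same order of 3 scalings, HSP90AA1 was 1.044, 0.649 and 0.867, HSPB8 1.205, 0.903 and 1.122, and CDKN1A 1.257, 0.757 and 0.976. HSP90AB1 was 0.038, 0.336 and 0.555. After quantile and hybridization control scaling MSMO1 was 0.981 and 0.659 and HSPE1 0.159 and 0.198, and after median and hybridization control scaling RBL1 was 0.087 and 0.306. CDKN1B was 0.055 after quantile normalization, and CRYAB 0.068 and GADD45B 0.209 with hybridization controls centred. For JQ1 minus TAE684 arrays BRD3 was -0.019 after quantile normalization, and PROM1 was 0.396 without a filter, where a brighter probe set can stand for the gene. For ribosomal protein genes the direction and the call of camera turned, and the sign of the list's value did not. In TAE684 minus sensitive arrays the list went from lower (adjusted p = 0.470) to higher with medians (2.6e-17) or hybridization controls (2.6e-17) centred, and in JQ1 minus TAE684 arrays from higher (0.00102) to lower with medians (0.00925) or hybridization controls (4.4e-07) centred, and after quantile normalization, without a call (0.435). Their mean minus that of all genes was 0.539 in TAE684 minus sensitive arrays on the deposited scale and with medians or hybridization controls centred, and in JQ1 minus TAE684 arrays -0.251 on the same 3 scales and -0.046 after quantile normalization. Differences of dim genes are uncertain in size, and log2(value + 1) compresses them to a small extent.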

Other observations

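The tests of the wrong-label and JQ1-return explanations and both tests of the lower signals were chosen after the results were seen, the first 2 of them in place of earlier tests whose results were known. HSP90AA1, HSPB8, CDKN1A, GADD45G, HMGCS1 and MSMO1 were chosen after their values were seen, as members that moved. Further gene groups differed between resistant TAE684 and sensitive arrays relative to the other genes of an array, and the heat shock, inhibitor and cholesterol lists did not pass on the deposited scale (adjusted p = 0.293, 0.153 and 0.423). Heat shock and proteostasis genes had 10 of 18 higher and 1 lower (11 and 1 adjusted over the list alone), against 0 higher and 12 lower on the deposited scale, camera adjusted p = 0.00549, and adjusted p = 0.589 with an estimated correlation. The 4 members with the smallest p on the deposited scale were not among those that rose: HSPB1 was lower (relative log2 difference -1.25), and CRYAB (-0.24), HSPE1 (0.16) and HSP90AB1 (0.04) did not pass. The chaperone gene HSP90AA1 was higher by 1.04 and HSPB8, a small heat shock protein, by 1.21, against -0.31 and -0.05 on the deposited scale.

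Cell cycle inhibitors had 7 of 13 higher and 0 lower in TAE684 arrays (7 and 0 adjusted over the list alone), against 1 higher and 9 lower on the deposited scale, camera adjusted p = 0.0121, and adjusted p = 0.589 with an estimated correlation. Their members with the smallest p did not pass as relative values: RBL2 (-0.45), CDKN1B (0.06), GADD45B (-0.26) and RBL1 (-0.07). CDKN1A was higher by a relative 1.26, against -0.20 on the deposited scale, and GADD45G by 2.41, whose deposited-scale call ended without sensitive replicate 1 (adjusted p = 0.110), sensitive replicate 2 (0.123) or TAE684 replicate 2 (0.0922). Cholesterol synthesis and uptake genes had 7 of 20 higher and 2 lower (10 and 2 adjusted over the list alone), against 0 higher and 15 lower on the deposited scale, camera adjusted p = 0.0353, and adjusted p = 0.740 with an estimated correlation. Here too the members with the smallest p did not rise, with PMVK (-0.85) and the regulator SREBF1 (-0.65) lower and EBP (-0.10) and FDPS (-0.04) not passing, while HMGCS1 (1.35) and MSMO1 (0.98) were higher. In JQ1 minus TAE684 arrays the list had 7 lower and 3 higher (the same adjusted over the list alone), against 1 lower and 10 higher on the deposited scale, camera adjusted p = 0.0421, and adjusted p = 0.782 with an estimated correlation. There PMVK (0.89), SREBF1 (0.51) and TM7SF2 (0.53) were higher, MVD (0.29) did not pass, and HMGCS1 (-2.25) and MSMO1 (-1.64) were lower. The HMGCS1 call on the deposited scale ended without JQ1 replicate 2 (adjusted p = 0.0794) and with the mean of a gene's probe sets (0.0557).

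Glycolysis and hypoxia genes had 14 of 29 lower, 4 higher and 11 not passing in TAE684 arrays (15 and 4 adjusted over the list alone; camera adjusted p = 0.0453, and adjusted p = 0.859 with an estimated correlation). The glucose transporter SLC2A1 had a relative log2 difference of -1.39, VEGFA -1.55, GPI -0.82 and LDHA -0.66. Histone genes had 17 of 47 lower and 3 higher (18 and 3 adjusted over the list alone), camera adjusted p = 0.00843, and adjusted p = 0.859 with an estimated correlation. HOX genes had 7 of 21 lower and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 0.0453, and adjusted p = 0.859 with an estimated correlation), and chromatin modifiers had 8 of 52 higher and 0 lower, against 1 higher and 46 lower on the deposited scale (7 and 0 adjusted over the list alone after quantile normalization; camera adjusted p = 0.0453, and adjusted p = 0.589 with an estimated correlation). On the deposited scale the glycolysis, histone, HOX and chromatin lists did not pass (adjusted p = 0.0837, 0.0837, 0.288 and 0.485). Marker lists of other cell types did not pass in that comparison, with adjusted p = 0.961 for Schwann or glial, 0.908 for fibroblast, 0.205 for immune, 0.942 for endothelial and 0.343 for epithelial markers. MYCN lay at the 99.2nd percentile of genes or above on each of the 6 arrays.

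The profile of the arrays labelled resistant JQ1 lay closer to the sensitive arrays than to the resistant TAE684 arrays. An untreated sensitive sample under a wrong label is argued against by genes listed in advance for a rise under BET inhibition, since 11 of 15 were higher than in sensitive arrays and 1 was lower after quantile normalization, the scale for which the bound of over 6 more members higher than lower was written. On the deposited scale 7 were higher and 1 lower, which does not pass that bound. By this count the argument holds on the first scale alone. Of all 14785 genes 83 were called higher on the deposited scale. Camera called the list higher relative to all genes there (adjusted p = 4.1e-15, and adjusted p = 0.997 with an estimated correlation). A candidate explanation that stays open is that these arrays came from JQ1-treated cells without the regional differences of the resistant cells: the median share of a window shift kept in JQ1 arrays was 0.136, with a share under 0.25 set beforehand for this explanation and over 0.75 against it, and it was 0.082 in the 47 windows seen on both TAE684 arrays. The share was not low everywhere: it ranged from -0.398 to 0.594, and 6 windows past the thresholds of both comparisons, 0.159 and 0.112, kept 0.444 to 0.551. Their medians were 0.16 to 0.27 on JQ1 replicate 1 and -0.08 to 0.05 on replicate 2. On TAE684 arrays they were 0.305 to 0.459 on replicate 1 and 0.075 to 0.207 on replicate 2. In both groups these shifts were thus larger on the arrays numbered 1. A return of the resistant cells under JQ1 cannot be told apart from that candidate explanation, since no untreated resistant array was used here. Whether the regional shifts are stable in these cells was not measured either. A return was taken, after the results were seen, to need a median share over 0.75, which presumes stable shifts. At 0.136 the share did not reach that bound. A return was also taken to leave genes lower by 2-fold lower more often than all genes, which was met. Of the genes lower by 2-fold in TAE684 arrays 39.7% were still lower than in sensitive arrays, against 8.6% of all genes. Of those higher by 2-fold 11% were still higher, against 6% of all genes. This is no sign that the higher genes were kept, since 61 of 555 were still higher and 73 were called lower than in sensitive arrays. Both comparisons share the sensitive arrays, which by itself raises these shares by an amount that was not measured. DNA copy number was not analysed here.

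The regional shifts of the TAE684 arrays were set against a trend of the fold change with signal intensity. A loess trend on mean signal was removed from the quantile-normalized differences, the scale on which the windows were found. After this 92.6% of the 81 windows stayed past the threshold, which argues against a trend left after that normalization as their cause. How much trend was left to remove was not measured. Gains and losses of chromosome segments in the resistant cells may produce such shifts, as a hypothesis that was not tested, and base composition, which could shift neighbouring genes together, was not tested either. The value of 92.6% bears on signal intensity alone.

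Most genes read lower on the resistant TAE684 arrays on the deposited scale. Less labelled RNA on these arrays is argued against by the hybridization controls, which are added after labelling and differed by -1.13 ± 0.36 (SD over 18 probe sets), while the ERCC spike-in differed by -0.05. Genes of like intensity minus these controls gave a mean log2 difference of 0 ± 0.09 (SD over the same 18), which is consistent with more spike-in RNA per unit of cell RNA on an array scale set by the spike-in. Whether more spike-in was added or the cells held less RNA stays open. No biological explanation was tested for this shift.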
